A study of Arabidopsis thaliana with 18 samples.

How the data were processed

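Transcript levels were measured with 18 Affymetrix arrays in seedlings of Arabidopsis thaliana, ecotype Columbia. Wild-type seedlings and a double mutant lacking the basic helix-loop-helix transcription factors PIF4 and PIF5 (pif4pif5) were compared. Per the labels, seeds were kept in the cold for 3 days and given 3 h of red light at 50 µmol/m2/s, and seedlings then grew in the dark for 3 days. They were harvested from darkness, after 1 h of far-red light at 0.5 µmol/m2/s, or after 24 h of far-red light at 5 µmol/m2/s. Duration and fluence rate changed together, so the labels allow no separation of one from the other. By the labels, darkness lasted 3 days in every group, so seedlings given 24 h of far-red light were older at harvest than the dark ones. No dark group of that age was included, so age is not separable at 24 h either. Each of the 6 groups had 3 replicates, lettered A, B and C. The labels state that 100 ng of total RNA was amplified and labelled with biotin.

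The deposited values are log2 signal intensities that the authors obtained by robust multi-array averaging (RMA), as their processing notes state. The version, the background model and the probe annotation of that step are not given in the sources used here. The values were used as deposited, without further normalization. The table held 22810 probe sets, of which 64 were Affymetrix controls and 22746 were tested. Genes were assigned with the probe table supplied for the platform: 13513 of the tested probe sets named 1 gene, 503 named several and 8730 named none. Of the single-gene probe sets, 13436 matched a locus in the reference gene table of assembly TAIR10.1, which served for symbols and for the order of neighbouring genes. They stood for 13356 distinct genes. For 11885 of their loci the table gave the locus tag as the symbol. PIF4 and PIF5 (listed there as PIL6) had no probe set assigned to them, so the genotype labels could not be checked on the mutated genes.

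A linear model with 1 mean per group was fitted to all 18 arrays with limma 3.58.1 in R 4.3.3 (with statmod 1.5.0, on which limma draws), with empirical Bayes moderation (12 residual and 5.91 prior degrees of freedom). Adjusted p values are Benjamini-Hochberg values within a comparison, and a probe set was called when its adjusted p was under 0.05. The comparisons were 1 h and 24 h of far-red light against darkness in each genotype, the genotypes against each other in each condition, 24 h against 1 h in wild type, and the interactions of genotype with 1 h and with 24 h of far-red light. All changes are log2 values of the first-named group minus the second, with the standard error (SE) of the model, and n = 3 arrays per group throughout. An exact test of 3 arrays against 3 has a smallest two-sided value of 0.1, so probe sets were tested with the variance shared across probe sets only.

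Lists of genes were fixed before the data were examined, together with the comparisons, the thresholds and the main alternatives. They were photosystem and light harvesting, chlorophyll synthesis, carbon fixation, photoprotection, carotenoid and plastid isoprenoid, plastid gene expression and greening regulators, phytochromes and their partners, light signalling transcription factors, shade avoidance, auxin response, brassinosteroid, gibberellin, ethylene, type-A response regulators, cell wall expansion, flavonoid and anthocyanin, circadian clock, dark and sugar starvation, seed storage and reserve use, stress and handling, and root markers. A gene counted as measured when a probe set named it alone. Most genes of the fixed lists had no such probe set. Each list result therefore covers only the measured members and not the whole pathway. Lists with at least 3 measured genes were tested as sets with camera (limma), with the preset correlation of 0.01 between genes and again with a correlation estimated from the data. In all, 90 such tests were made, 9 lists in 10 comparisons, and adjusted within each comparison. Gene families, taken from shared symbol stems with at least 5 measured members, and the genes of the plastid genome were tested in the same way after the data had been seen. Whether the genotype effect ran along the far-red response was tested with fry on signed sets of called probe sets, in 3 pairs of comparisons that share no array.

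Genes are named by a fixed rule. PIF4 and PIF5 came first, then up to 6 of the largest rises and 6 of the largest falls among called single-gene probe sets whose groups did not overlap, then up to 3 called members of each list. A list without a called member gave at most the member of lowest p, as not called. A gene named in one comparison was followed through the others. At most 2 called probe sets without an assigned gene are given in each direction.

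The procedure was tested on simulated data, with independent normal noise of each probe set's fitted spread and 200 probe sets changed in 1 group. Real arrays also share deviations, which such data lack. The simulated spread was the same in all groups, so the shares below do not rank the comparisons of 2 groups by sensitivity. Differences between those shares come from the probe sets and noise drawn. In the real arrays the median residual SD, around the group means, was 0.258 in darkness, 0.134 at 1 h and 0.196 at 24 h. At a change of 1 on the log2 scale limma recovered 83.6% for 1 h and 82.1% for 24 h of far-red light in wild type, 95.5% for the genotypes in darkness, 76.1% for the genotypes at 24 h and 34.3% for the interaction at 24 h. At a change of 0.5 the shares were 7.46%, 8.96%, 10.4%, 13.4% and 1.49%. At a change of 2 they were 98.5%, 98.5%, 100%, 98.5% and 93.9%. Between 5 and 8 unchanged probe sets were called. A set test on simulated data found the list that had been shifted by 0.5 and 0 of the others. The fry test of a genotype effect set against the light response was called at a slope of -0.5 and not at a slope of 0.

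Replicate letters recur in every group. Whether arrays of the same letter deviate together was checked from the correlations of their deviations from the group means. Among the compared groups, every same-letter value passed 0.1 for wild type at 1 h and 24 h (0.103, 0.151 and 0.304) and for no other pair compared directly. It also did for wild type in darkness and the mutant at 24 h (0.192, 0.343 and 0.311), which meet in the interaction. In the remaining pairs at least 1 letter stayed under 0.1, so the main fit treats the letters as running numbers. This rule does not show that letters carry no shared effect. Mean same-letter correlations ranged from -0.0105 to 0.282, the lowest being the only negative one. A fit with the replicate as a block was therefore kept as an alternative. Other alternatives were the removal of the 40% dimmest probe sets, a trended and robust prior, quantile normalization, a shift of all arrays to one median, fits on the compared groups only, a 2-fold minimum, the removal of probe sets with several genes or none, every single-gene probe set of a list, and leaving out each array in turn. Array weights and the removal of the 3 arrays of lowest weight were added after the data had been seen. Control probe sets were left out of these tests, used for array checks and tested apart with the same model. The precision of every value is limited by the number of arrays.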

Results

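The series holds 18 array profiles of dark-grown Arabidopsis seedlings, 3 for each combination of genotype (wild type or pif4pif5) and condition (darkness, 1 h of far-red light or 24 h of far-red light). PIF4 and PIF5 are transcription factors that bind active phytochrome and promote growth in darkness and shade. The design asks which transcripts respond to far-red light, and how the loss of both factors changes transcript levels in darkness and during the response. At 24 h the duration, the fluence rate and the age of the seedlings differ together, so changes there cannot be assigned to far-red light alone. Each array gives log2 intensities for 22746 probe sets besides the controls. The labels do not say that replicates were separate cultures, so the p values measure only the spread between these samples, which may be technical. The number of arrays limits the precision.

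The median over all tested probe sets was 6.16 on wild-type dark replicate C and between 5.6 and 5.88 on the other 17 arrays. The 27 bacterial controls that were not spiked in averaged 3.67 on that array, 3.37 on wild-type dark replicate B and between 3.09 and 3.29 on the other 16. Both arrays belong to the group against which the wild-type light responses and the genotype effect in darkness are measured. Correlations between replicates ranged from 0.967, for wild-type dark replicates B and C, to 0.997. Over all tested probe sets the groups did not overlap for 11.7% at 1 h and 19.7% at 24 h in wild type, 17.6% and 31.8% in the mutant, 30.3% for 24 h against 1 h, and 6.91%, 17.1% and 13.2% between the genotypes in darkness, at 1 h and at 24 h, where chance gives 10%. The median change of all probe sets was -0.12 for 1 h and -0.12 for 24 h of far-red light against darkness in wild type, and it lay between -0.07 and 0.02 in the other comparisons between groups. In wild type quantile normalization moved it to -0.01 at 1 h and -0.03 at 24 h, and a shift to one median moved it to -0.04 and -0.02. In the mutant at 24 h that shift moved it from -0.04 to 0.11.

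**Figure D1:**
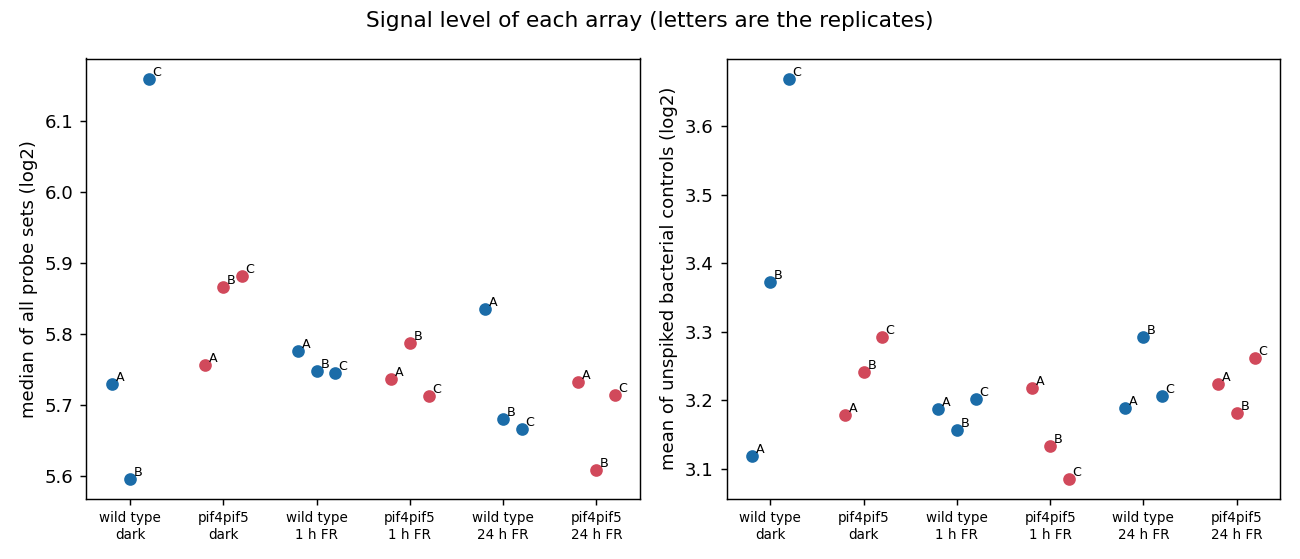
Left, the median log2 intensity of all tested probe sets on each array; right, the mean log2 intensity of the 27 unspiked bacterial controls, with wild type in blue, pif4pif5 in red and letters for replicates. Wild-type dark replicate C stands highest in both, at 6.16 and 3.67.

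After 1 h of far-red light, wild-type seedlings had more transcript of a light signalling factor and a flavonoid enzyme, and less of an auxin-response repressor and an expansin. HYH, a bZIP factor close to the photomorphogenesis regulator HY5, rose by 1.65 (SE 0.24, 3.13-fold, adjusted p = 9.14e-04). UGT78D2, a flavonoid glucosyltransferase, rose by 1.58 (SE 0.21, 2.99-fold). IAA29, an auxin-response repressor of the Aux/IAA family, fell from 8.54 ± 0.32 to 6.05 ± 0.23 (SD, n = 3), which is 5.58-fold (adjusted p = 1.27e-06). The expansin gene EXPA9, whose product loosens cell walls, fell by 0.83 (SE 0.18, adjusted p = 0.0303). The largest rises were those of AT3G56290, from 5.29 ± 0.22 to 7.93 ± 0.32 (6.25-fold), AT1G64500 by 2.5, AT3G02910 by 2.25, AT3G21670 by 2.04, AT1G06000 by 1.73 and AT4G24700 by 1.65. Besides IAA29, the largest falls were those of AT5G57760 (-1.92), AT5G67020 (-1.58), AT4G35720 (-1.58), AT4G16670 (-1.39) and AT5G02580 (-1.15). The clock gene GI rose by 1.08 (SE 0.23, adjusted p = 0.0258). Its call was lost without wild-type dark replicate B and without any 1 of the 1 h replicates (adjusted p up to 0.178). That of EXPA9 was lost without wild-type dark replicate C or 1 h replicate A or B (up to 0.219).

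At 1 h the auxin response list had 5 measured genes, of which 1 fell (IAA29) and 3 did when adjusted over the list alone. Its median was -0.54 and the list was lower as a set (adjusted p = 3.23e-04, but 0.0698 with an estimated correlation). Of 6 measured shade avoidance genes 1 fell, again IAA29, and 1 when adjusted over the list alone. The median of that list was -0.26 (adjusted p = 0.014, but 0.0858 with an estimated correlation and 0.332 without wild-type dark replicate A). None of the 7 photosystem and light harvesting genes was called, 3 were when adjusted over the list alone, and the list stood higher by a median of 0.35 (adjusted p = 1.63e-07, but 0.0691 with an estimated correlation). PSAN, a photosystem I subunit, differed by 0.42 (SE 0.13, adjusted p = 0.192). Of the 4 flavonoid and anthocyanin genes UGT78D2 rose, with a list median of 0.12 (adjusted p = 0.00331, but 0.0858 with an estimated correlation and 0.0511 without wild-type dark replicate C; median 0.06 without dark replicate A and 0.19 without 1 h replicate C). The 3 carbon fixation genes had a median of 0.22 and 0 were called (adjusted p = 0.00875, but 0.0858 with an estimated correlation, and 0.0929 and 0.104 without wild-type dark replicates A and C). The chlorophyll synthesis list had a median of -0.00, a mean of 0.01 and an upward test direction that was not called (adjusted p = 0.171). Without wild-type dark replicate B its median was 0.11, and without 1 h replicate C it was 0.06, with the list called higher in both fits (adjusted p = 3.23e-04 and 0.0291). The cell wall expansion list (median -0.05, 1 of 9 fell) was not called (adjusted p = 0.65). Its median turned positive under quantile normalization (0.04) and after a shift of all arrays to one median (0.02).

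In total limma called 179 probe sets at 1 h in wild type, 124 higher and 55 lower. The share of higher calls was 69.3%, against 79.3% with quantile normalization and 79.0% after a shift to one median. The count was 1685 (195 higher and 1490 lower) without wild-type dark replicate A, which leaves replicates B and C as the dark reference. It was 281 without dark replicate C, 103 without 1 h replicate A and 98 without 1 h replicate B. Other alternatives gave from 39 (probe sets of several genes or none left out) to 243 (arrays shifted to one median).

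After 24 h of far-red light, the measured photosystem and carbon fixation genes were higher in wild type, and TUB1, EXPA9 and ICL were lower. All 7 measured photosystem and light harvesting genes rose, by a median of 1.77 (7 when adjusted over the list alone; adjusted p = 4.17e-20, and 0.00156 with an estimated correlation). PSAN rose from 9.68 ± 0.02 to 11.96 ± 0.06 (SD, n = 3), or 4.86-fold, PSAE-1 by 1.88 (SE 0.18) and the photosystem II gene PSBY by 1.87 (SE 0.15). All 3 carbon fixation genes rose, by a median of 1.35 (adjusted p = 1.6e-06, and 0.00614 with an estimated correlation). They were RCA, the activase of Rubisco, by 1.56 (SE 0.15, 2.94-fold), SBPASE of the Calvin cycle by 1.35 (SE 0.18) and PRK by 0.53 (SE 0.17, adjusted p = 0.0446). The beta-tubulin gene TUB1 fell by 2.76 (SE 0.27, 6.76-fold), EXPA9 by 2.74 (SE 0.18, 6.70-fold), and ICL, the isocitrate lyase of the glyoxylate cycle, by 1.11 (SE 0.16, 2.16-fold).

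Of 8 chlorophyll synthesis genes 4 rose at 24 h, and 5 rose and 1 fell when adjusted over the list alone. HEME1, a uroporphyrinogen decarboxylase gene, rose by 1.2 (SE 0.16, 2.3-fold), CHLM by 0.88 (SE 0.13) and CHLI2, a subunit gene of magnesium chelatase, by 0.74 (SE 0.22, adjusted p = 0.0394). The list median was 0.64 (adjusted p = 4.9e-04, but 0.0973 with an estimated correlation and 0.0683 without wild-type dark replicate C). Of 6 shade avoidance genes 3 fell and 4 did when adjusted over the list alone, with a median of -0.73 (adjusted p = 0.0107, but 0.0973 with an estimated correlation and 0.09 without wild-type dark replicate A). They were XTH33 (-1.59, SE 0.32), a xyloglucan-modifying enzyme gene, the bHLH gene BIM1 (-0.76, SE 0.18) and the homeobox gene HAT2 (-0.72, SE 0.14). Of 9 cell wall expansion genes 3 fell, EXPA9, XTH33 and XTH19 (-2.05, SE 0.51), and 4 did when adjusted over the list alone, while the list was not called (median -0.14, adjusted p = 0.084). XTH19 has a close paralog, XTH18, and signal of the pair may mix. The list was called with a lower direction without wild-type dark replicate C (adjusted p = 0.0149) or 24 h replicate B (0.00817). None of the 5 auxin response genes was called (median -0.34, adjusted p = 0.561), GH3.3 being at -0.38 (adjusted p = 0.245). Of the 4 flavonoid genes UGT78D2 rose by 1.02 (SE 0.21), with the list not called (median 0.28, adjusted p = 0.123, and 0.0486 without wild-type dark replicate B). HYH rose by 1.58 (SE 0.24) and GI by 0.73 (SE 0.23, adjusted p = 0.0451). The call of XTH19 was lost without wild-type dark replicate A or B or 24 h replicate A or C (adjusted p up to 0.0838), and those of CHLI2 and HEME2 (0.63, adjusted p = 0.0489) without dark replicate A or C or 24 h replicate A or B (up to 0.176 and 0.217). The calls of PRK and GI were lost without any 1 of the 6 arrays except wild-type dark replicate C (up to 0.138 and 0.133).

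The largest rise at 24 h was that of AT5G48490, from 5.64 ± 0.29 to 9.98 ± 0.40 (20.2-fold), followed by AT2G29290 (3.1), AT1G21500 (3.09), AT2G34620 (2.92), AT5G16030 (2.79) and AT5G35970 (2.79). The largest falls besides TUB1 and EXPA9 were those of AT2G34020 (-3.93, SE 0.18, 15.2-fold), AT4G11610 (-2.57), AT4G22490 (-2.46) and AT1G70270 (-2.31). In total 2559 probe sets were called, 1018 higher and 1541 lower. The direction of the balance depended on scaling: 39.8% of the calls were higher in the deposited values, 53.2% with quantile normalization (1473 higher and 1297 lower) and 63.6% after a shift to one median (1506 and 863). The balance also turned without 1 array: 1855 were higher and 1254 lower without dark replicate C, 883 and 793 without 24 h replicate C (1676 in all). Without dark replicate A there were 910 and 2904. Other alternatives gave from 756 (fit on the compared groups only) to 3051 (replicate block).

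**Figure D2:**
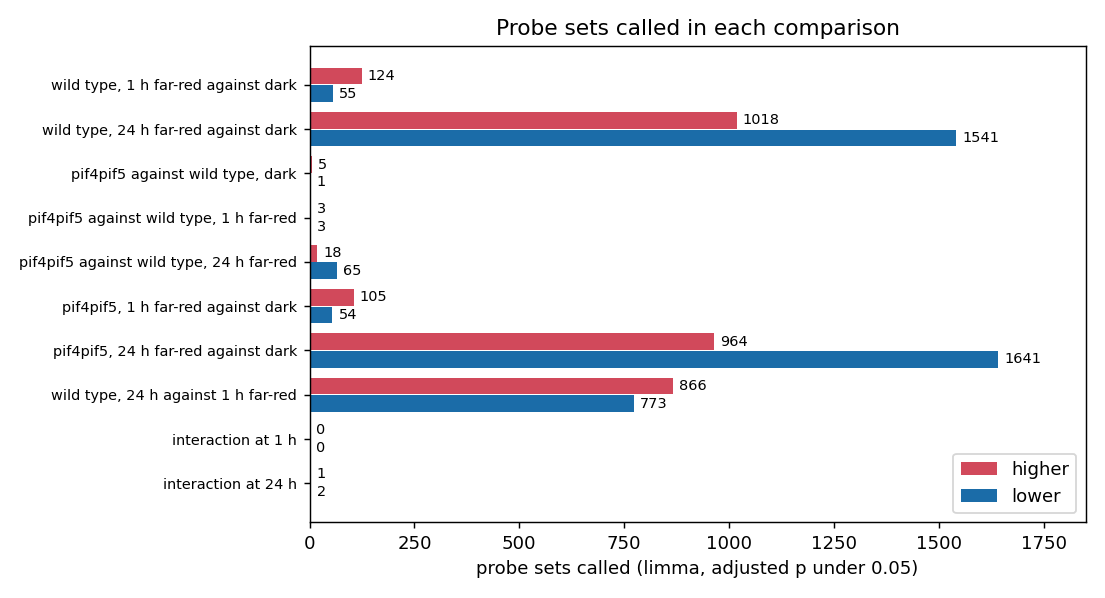
Number of probe sets called higher and lower (adjusted p under 0.05) in each comparison between groups and each interaction, 3 arrays per group. The 24 h comparisons with darkness hold 2559 calls in wild type and 2605 in pif4pif5, and the genotype comparisons 6, 6 and 83.

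Between 1 h and 24 h of far-red light in wild type, photosystem and carbon fixation genes rose, and IAA29 returned towards its dark level. IAA29 rose from 6.05 ± 0.23 to 8.19 ± 0.34 (SD, n = 3), which is 4.40-fold (adjusted p = 2.97e-06), and at 24 h it differed from darkness by -0.34 (SE 0.21, adjusted p = 0.322). All 7 photosystem and light harvesting genes rose, and all 7 when adjusted over the list alone, by a median of 1.47 (adjusted p = 3.87e-16, and 0.00407 with an estimated correlation). PSAN rose by 1.86, PSAE-1 by 1.82 and PSBW by 1.48. RCA (1.39) and SBPASE (1.13) rose among the 3 carbon fixation genes, with a list median of 1.13 (adjusted p = 1.44e-04, and 0.0245 with an estimated correlation). Of 8 chlorophyll synthesis genes 4 rose, and 5 when adjusted over the list alone, HEME1 by 1.19, CHLM by 0.83 and CHLI2 by 0.80 (median 0.58, adjusted p = 0.00695, but 0.226 with an estimated correlation). CHLI2 and HEME2 (0.68) lost their calls without any 1 of the 6 arrays except 24 h replicate C (adjusted p up to 0.156 and 0.198), and LHCB4.3 of the photosystem list lost its call without 1 h replicate A or 24 h replicate A or B (up to 0.058). HYH (-0.06), UGT78D2 (-0.56) and GI (-0.35) were not called.

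Of 9 cell wall expansion genes 3 fell between 1 h and 24 h: XTH19 (-2.42), EXPA9 (-1.91) and XTH33 (-1.55). The list median was -0.09 (adjusted p = 0.0286, but 0.367 with an estimated correlation and 0.347 without 24 h replicate C), and -0.18 without 24 h replicate A. In the shade avoidance list 1 gene rose (IAA29) and 3 fell, among them BIM1 (-0.85), and the list was not called (median -0.33, adjusted p = 0.455). HAT2 of that list lost its call without 1 h replicate A or B or 24 h replicate A or C (adjusted p up to 0.142). The auxin response list stood higher by a median of 0.31 with IAA29 as the called member (adjusted p = 0.0273, but 0.226 with an estimated correlation and 0.0614 without 24 h replicate B). Its median was 0.17 without 1 h replicate C, 0.17 without 24 h replicate A and 0.52 without 24 h replicate C. The flavonoid list was not called (median -0.11). ICL fell by 0.99 (SE 0.16) and TUB1 by 2.86 (SE 0.27). The largest rises were those of AT5G48490 (3.75, SE 0.31), AT5G16030 (2.87), AT1G21500 (2.73), AT4G28780 (2.72), AT4G18740 (2.72) and AT5G44580 (2.69). AT2G34020 (-3.66), AT4G22490 (-2.46), AT1G06000 (-2.29) and AT4G11610 (-2.28) fell furthest besides the genes above. In total 1639 probe sets were called, 866 higher and 773 lower. The count was 1077 without 1 h replicate A, and without 24 h replicate A the balance turned, with 661 higher and 743 lower. Other alternatives gave from 609 (2-fold minimum) to 3551 (array weights). The higher share was 52.8%, and 62.4% after a shift to one median.

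In pif4pif5, 1 h of far-red light changed many of the transcripts that it changed in wild type. AT3G56290 rose by 2.65 (SE 0.26), AT1G64500 by 2.43, AT3G21670 by 2.14, AT1G06000 by 2.05 and AT3G02910 by 1.94. UGT78D2 rose by 1.76 (SE 0.21, 3.40-fold), HYH by 1.57 (SE 0.24) and GI by 1.56 (SE 0.23). IAA29 fell by 2.39 (SE 0.21, 5.25-fold), AT5G02580 by 1.79, AT5G50335 by 1.72, AT5G57760 by 1.65, AT4G35720 by 1.46 and AT4G16670 by 1.3. EXPA9 (-0.49, adjusted p = 0.537) was not called. The call of AT5G57760 was lost without mutant dark replicate A or B or 1 h replicate B or C (adjusted p up to 0.0739).

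Of the 4 flavonoid genes 1 rose in the mutant at 1 h and 3 did when adjusted over the list alone, with a median of 0.83 (adjusted p = 2.01e-06, and 0.0269 with an estimated correlation). Of the 5 auxin response genes 1 fell and 2 did when adjusted over the list alone (median -0.35, adjusted p = 9.5e-06, and 0.0269 with an estimated correlation). The photosystem list stood higher by 0.23 with 0 called and 1 when adjusted over the list alone (adjusted p = 9.5e-06, but 0.064 with an estimated correlation), PSBY being at 0.51 (SE 0.15, adjusted p = 0.272). Other lists called with the preset correlation were carbon fixation (median 0.24, 0.00534, but adjusted p = 0.0661 with an estimated correlation) and shade avoidance (-0.16, 0.0225, but adjusted p = 0.101 with an estimated correlation). The latter was lost without mutant dark replicate A (adjusted p = 0.0533) or 1 h replicate B (0.0696). Chlorophyll synthesis (median 0.15, adjusted p = 0.0259, but 0.269 with an estimated correlation) was lost without dark replicate B (0.108) or 1 h replicate A (0.0859) or B (0.0919). Without mutant 1 h replicate C the medians were 1.25 for flavonoid, 0.37 for photosystem, 0.27 for chlorophyll synthesis and 0.39 for carbon fixation genes, the last at 0.16 without 1 h replicate A or B. The cell wall list was not called, with a median of -0.02, a mean of 0.04 and an upward test direction (adjusted p = 0.572). In total 159 probe sets were called, 105 higher and 54 lower. The count was 103 without dark replicate A, 98 without dark replicate B, 99 without 1 h replicate A and 84 without 1 h replicate B. Other alternatives gave from 30 (probe sets of several genes or none left out) to 474 (array weights). The higher share was 66.0%, and 80.5% after a shift to one median.

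After 24 h of far-red light in pif4pif5, photosystem genes were higher and shade avoidance genes lower than in the dark mutant. Of 7 photosystem and light harvesting genes 6 rose, and 6 when adjusted over the list alone, by a median of 1.29 (adjusted p = 2.47e-12, and 0.0121 with an estimated correlation). PSAN rose by 1.72 (SE 0.13, 3.29-fold), PSBY by 1.61 and PSBW by 1.53. The 3 carbon fixation genes rose, RCA by 1.13 (SE 0.15), SBPASE by 0.99 and PRK by 0.74 (list median 0.99, adjusted p = 2.76e-05, and 0.0162 with an estimated correlation). HEME1 rose by 1.59 (SE 0.16, 3.01-fold), CHLI2 by 1.11 and CHLM by 0.98, among 4 of 8 chlorophyll synthesis genes that rose (6 when adjusted over the list alone; median 0.80, adjusted p = 2.62e-04, but 0.0711 with an estimated correlation). TUB1 fell by 3.32 (SE 0.27, 9.96-fold), EXPA9 by 2.75 (SE 0.18, 6.75-fold) and OLEO3, an oil body protein gene, by 2.93 (SE 0.22, 7.64-fold).

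Of 6 shade avoidance genes 5 fell in the mutant at 24 h, with a median of -1.07 (adjusted p = 3.54e-04, and 0.025 with an estimated correlation). They included XTH33 (-1.71), FHL (-1.43, SE 0.27), which acts in the nuclear import of phytochrome A, and HAT2 (-1.11). Of 9 cell wall expansion genes 5 fell and 6 did when adjusted over the list alone, among them XTH19 (-2.70) and XTH18 (-1.72), with a median of -0.50 (adjusted p = 2.76e-05, but 0.0652 with an estimated correlation). EXPA4 of that list lost its call without dark replicate A or B or 24 h replicate A or B (adjusted p up to 0.0619). Of 5 auxin response genes 2 fell, GH3.3, of an auxin-conjugating enzyme family, by 0.82 (adjusted p = 0.0106) and IAA29 by 0.70 (SE 0.21, adjusted p = 0.0349), and the list was not called (median -0.26, adjusted p = 0.185). UGT78D2 rose by 1.04 in a flavonoid list that was not called (median 0.20, adjusted p = 0.205). GI rose by 1.18, the type-A response regulator gene RR16 by 1.42 (SE 0.32, and 0.81 without 24 h replicate B), and ICL fell by 0.67 (SE 0.16, adjusted p = 0.0108). HYH was at 0.74 (SE 0.24, adjusted p = 0.0571) and became called without 24 h replicate B (adjusted p = 0.0403). GH3.3 lost its call without dark replicate C (adjusted p = 0.0544), IAA29 without dark replicate A or B or 24 h replicate B or C (up to 0.175), and ICL without dark replicate C or 24 h replicate B (up to 0.0738).

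The largest rises in the mutant at 24 h were those of AT5G48490 (3.38, SE 0.31, 10.4-fold), AT1G21500 (3.17), AT1G60590 (3.13), AT5G35970 (2.90), AT3G21670 (2.74) and AT4G18740 (2.68). Besides TUB1 and OLEO3, AT4G11610 (-3.96, SE 0.17, 15.5-fold), AT2G34020 (-3.83), the glycosyl hydrolase gene GH9B13 (-3.26) and AT4G22460 (-2.84) fell furthest. In total 2605 probe sets were called, 964 higher and 1641 lower. The higher share was 37.0%, but 49.4% with quantile normalization (1397 higher and 1432 lower) and 63.9% after a shift to one median (1791 and 1014). The count was 1543 without dark replicate B, and other alternatives gave from 869 (2-fold minimum) to 4607 (array weights).

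Responses of the 2 genotypes ran in the same direction for most of these probe sets. At 1 h, 122 probe sets were called in both with the same direction, 87 higher and 35 lower, where 0.572 and 0.131 are expected by chance, and 0 with opposite directions. Of the 179 called in wild type, 177 changed with the same sign in the mutant (98.9%; r = 0.968 across probe sets, with a slope of 0.910). At 24 h, 1573 were called in both with the same direction, 746 higher and 827 lower, where 43.1 and 111 are expected by chance, and 1 with opposite directions. Of the 2559 called in wild type, 2467 had the same sign in the mutant (96.4%; r = 0.935, slope 0.875). These correlations are across probe sets, which are not independent replicates, and the compared responses share no array.

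**Figure D3:**
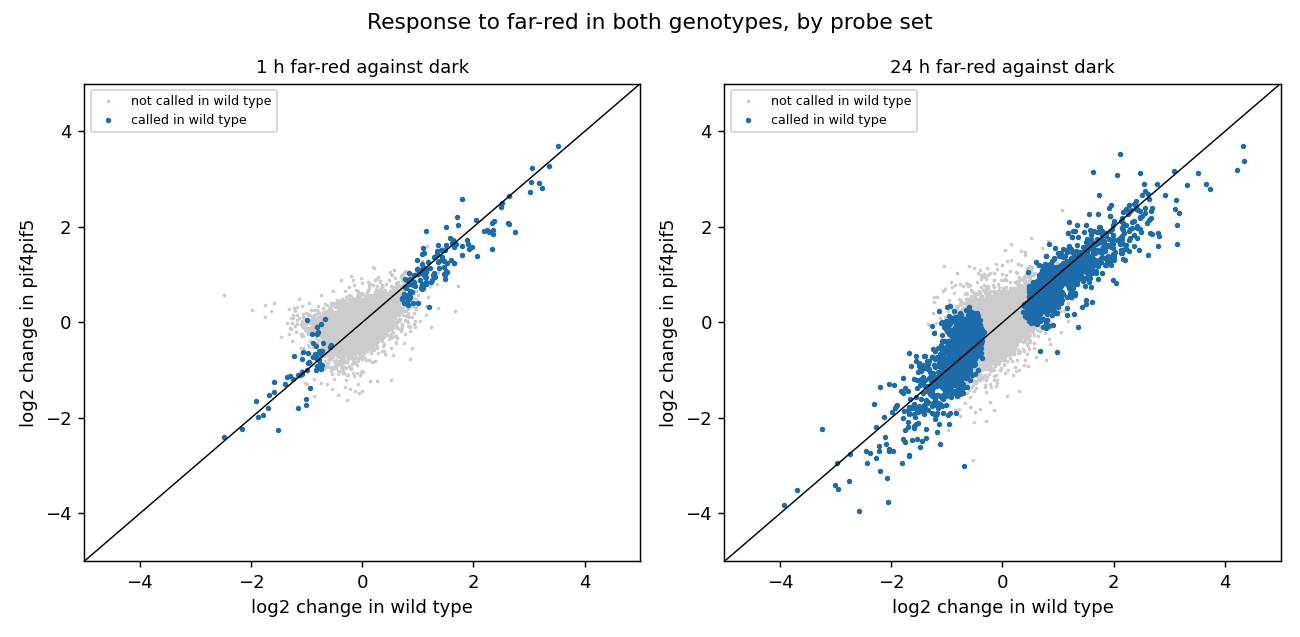
Log2 change under far-red light in wild type (horizontal) against that in pif4pif5 (vertical) at 1 h and 24 h, with 1 point per probe set, those called in wild type in blue and the line of equal change. Of the blue points 98.9% at 1 h and 96.4% at 24 h have the same sign on both axes.

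In darkness, few single transcripts were called between the genotypes, and photosynthesis genes stood slightly higher as a list. The dark arrays had the widest spread, with a median residual SD of 0.258, against 0.134 at 1 h and 0.196 at 24 h. The model gives all groups one spread, so its SE may be too small in darkness and too large at 1 h. A low count in darkness does not show that few transcripts differed. AT5G48490 was higher in pif4pif5, at 7.82 ± 0.50 against 5.64 ± 0.29 (SD, n = 3), or 4.54-fold (adjusted p = 0.0115). The 7 photosystem and light harvesting genes had a median difference of 0.63 with 0 called and 6 when adjusted over the list alone (adjusted p = 3.37e-14, and 0.00693 with an estimated correlation). PSAN differed by 0.66 (SE 0.13, adjusted p = 0.12) and became called without wild-type dark replicate A (adjusted p = 0.0229). The chlorophyll synthesis list stood higher by 0.26 with 0 called and 1 when adjusted over the list alone (adjusted p = 7.58e-05, but 0.0724 with an estimated correlation and 0.429 without wild-type dark replicate C; median 0.43 without replicate B), HEME1 being at 0.54 (adjusted p = 0.492). The carbon fixation list stood higher by 0.40 with 0 called and 2 when adjusted over the list alone (adjusted p = 0.00273, but 0.0724 with an estimated correlation, and 0.0552 and 0.14 without wild-type dark replicates A and C), RCA being at 0.40 (adjusted p = 0.578).

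Growth-related lists were not called between the genotypes in darkness: shade avoidance (median -0.26, adjusted p = 0.14, and 0.0488 without wild-type dark replicate B), auxin response (-0.27, adjusted p = 0.14) and cell wall expansion. For the last the median was -0.04, the mean -0.08, the test direction upward (adjusted p = 0.96), and the median 0.02 with quantile normalization. The flavonoid list was not called (0.14, adjusted p = 0.109, and 0.0084 without wild-type dark replicate B). HYH (0.72, adjusted p = 0.526) and GI (-0.54, adjusted p = 0.635) were not called. Of 6 called probe sets 5 were higher and 1 lower. The lower one has no assigned gene and differed by -3.56 in darkness, -4.57 at 1 h and -5.01 at 24 h (adjusted p = 2.98e-05, 5.11e-07 and 5.53e-08). It read 3.21 to 3.79 on the mutant arrays and 6.41 to 8.84 on those of wild type. PIF4 and PIF5 have no assigned probe set, so this one may measure a mutated gene itself, which could not be checked. Among the higher ones another without an assigned gene differed by 1.81 (adjusted p = 6.84e-04). At an unadjusted p under 0.05 there were 1654 probe sets. The count was 702 (44 higher and 658 lower) without wild-type dark replicate A, 23 without wild-type dark replicate C, and 3, 2 and 3 without mutant replicates A, B and C. Fits on the compared groups only gave 0 by limma, a trended and robust prior 17, the replicate block 23 and array weights 3. The call of AT5G48490 was lost without mutant replicate A or B (adjusted p up to 0.129). The median over all probe sets differed by -0.05, 11 were called with quantile normalization, and 6 after a shift to one median (4 higher and 2 lower).

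At 1 h of far-red light, lists of photosynthesis and pigment genes were higher in the mutant than in wild type, while 3 single genes were called. AT5G48490 was higher, at 8.15 ± 0.65 against 6.23 ± 0.50 (SD, n = 3; 3.80-fold, adjusted p = 0.0402). AT5G02580 was lower, at 5.51 ± 0.01 against 6.74 ± 0.21 (2.35-fold, adjusted p = 0.00237), and AT5G26270 by -1.12 (SE 0.17, adjusted p = 0.0237). The photosystem list stood higher by a median of 0.49 (0 called, 5 when adjusted over the list alone; adjusted p = 5.35e-13, and 0.00987 with an estimated correlation), PSAE-1 being at 0.91 (SE 0.18, adjusted p = 0.139). The chlorophyll synthesis list stood higher by 0.43 (0 called, 1 when adjusted over the list alone; adjusted p = 2.72e-07, and 0.0314 with an estimated correlation), with HEME1 at 0.70 (SE 0.16, adjusted p = 0.246). All 4 flavonoid genes were above their wild-type level without a call, 2 being called when adjusted over the list alone (median 0.60, and 0.93 without mutant replicate C; adjusted p = 1.12e-04, and 0.037 with an estimated correlation), with CHIL, a chalcone isomerase-like gene, at 1.1 (SE 0.33, adjusted p = 0.561). The carbon fixation list stood higher by 0.45 (0 called, 2 when adjusted over the list alone; adjusted p = 8.73e-04, and 0.037 with an estimated correlation), with RCA at 0.45.

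Shade avoidance (median -0.12, adjusted p = 0.208), auxin response (-0.18, adjusted p = 0.0698, and 0.0137 without wild-type 1 h replicate C) and cell wall expansion genes (0.12, adjusted p = 0.152) were not called as lists between the genotypes at 1 h. In total 6 probe sets were called, 3 higher and 3 lower, and 923 had an unadjusted p under 0.05. The count was 52 (48 higher and 4 lower) without mutant replicate C, and it was 2 without wild-type replicate A, wild-type replicate C, mutant replicate A or mutant replicate B. It was 12 without the 40% dimmest probe sets, 16 with a trended and robust prior, 39 with the replicate block, 16 without the 3 arrays of lowest weight, 425 with array weights and 3 without probe sets of several genes or none. AT5G48490 lost its call without wild-type replicate A or C or mutant replicate A or B (adjusted p up to 0.488), and AT5G26270 without any 1 of the 6 arrays except mutant replicate C (up to 0.332). AT5G02580 kept its call with each array left out. After a shift to one median 6 probe sets were called, 2 higher and 4 lower.

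After 24 h of far-red light HEME1 was higher and AT5G02580 lower in the mutant than in wild type. HEME1 stood at 10.17 ± 0.15 against 9.24 ± 0.26 (SD, n = 3; 1.9-fold, adjusted p = 0.0154). AT5G02580 stood at 5.63 ± 0.20 against 7.67 ± 0.10 (4.1-fold lower, adjusted p = 6.68e-07). All 6 measured shade avoidance genes were lower by value, by a median of -0.46, with 0 called and 3 when adjusted over the list alone (adjusted p = 3.38e-04, but 0.0603 with an estimated correlation). All 9 cell wall expansion genes were lower by value, by a median of -0.37, with 0 called and 1 when adjusted over the list alone (adjusted p = 1.76e-04, but 0.122 with an estimated correlation). Their median was -0.17 without wild-type replicate B and -0.58 without C. The 5 auxin response genes had a median of -0.38 with 0 called and 2 when adjusted over the list alone (adjusted p = 0.00908, but 0.144 with an estimated correlation and 0.0546 without wild-type 24 h replicate B). Their median was -0.20 without mutant replicate A and -0.63 without B. The members of lowest p were FHL (-0.86, adjusted p = 0.304), EXPA8 (-0.68, SE 0.16, adjusted p = 0.0891) and GH3.3 (-0.70, SE 0.20, adjusted p = 0.193), and IAA29 was at -0.69 (SE 0.21, adjusted p = 0.251). EXPA8 and GH3.3 became called without wild-type 24 h replicate C (adjusted p = 0.00996 and 0.0431).

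Of 8 chlorophyll synthesis genes 1 rose relative to wild type (HEME1), 3 did when adjusted over the list alone, and 7 were above their wild-type level at 24 h (median 0.39, and 0.22 without wild-type replicate C; adjusted p = 1.92e-05, but 0.0668 with an estimated correlation). The photosystem list no longer differed as a set (median 0.18, adjusted p = 0.27), with 6 of 7 genes above wild type and LHCB4.3, whose paralogs LHCB4.1 and LHCB4.2 are close in sequence, at -0.71 (SE 0.19, adjusted p = 0.175). Adjusted over the list alone, LHCB4.3 was the 1 gene called. Carbon fixation (0.05, adjusted p = 0.424) and flavonoid genes (0.13, adjusted p = 0.313) were not called as lists.

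The largest rises in the mutant relative to wild type at 24 h besides HEME1 (0.93) were those of AT1G76110 (1.05), GH3.9 (1.04, SE 0.20), AT1G74070 (0.90), DI21 (0.87) and AT3G06470 (0.78). The largest falls besides AT5G02580 were those of AT5G57670 (-1.93, SE 0.29), AT4G35720 (-1.79), AT5G38710 (-1.78), AT3G55940 (-1.65) and AT4G25260 (-1.51). In total 83 probe sets were called, 18 higher and 65 lower. Among probe sets without an assigned gene one differed by -2.61 (adjusted p = 2.09e-09) and another by 1.51 (adjusted p = 7.33e-05). The count was 178 (15 higher and 163 lower) without wild-type replicate C, 21 and 24 without wild-type replicates A and B, and 55, 34 and 38 without mutant replicates A, B and C. Other alternatives gave from 13 (fit on the compared groups only) to 225 (array weights). Of the 12 named genes AT5G02580, AT5G57670, AT4G35720 and AT4G25260 kept their calls with each array left out. HEME1 lost its call without mutant replicate B (adjusted p = 0.077), and the other 7 lost theirs in 4 or 5 of the 6 fits. Calls were kept without wild-type replicate C or mutant replicate A for AT1G76110, AT5G38710 and AT3G55940 (adjusted p otherwise up to 0.251, 0.177 and 0.0839). They were kept without wild-type replicate C or mutant replicate C for DI21 (up to 0.175), and without wild-type replicate C or mutant replicate B for AT1G74070 (up to 0.121). GH3.9 kept its call only without mutant replicate B (up to 0.133) and AT3G06470 only without wild-type replicate C (up to 0.213).

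**Figure D4:**
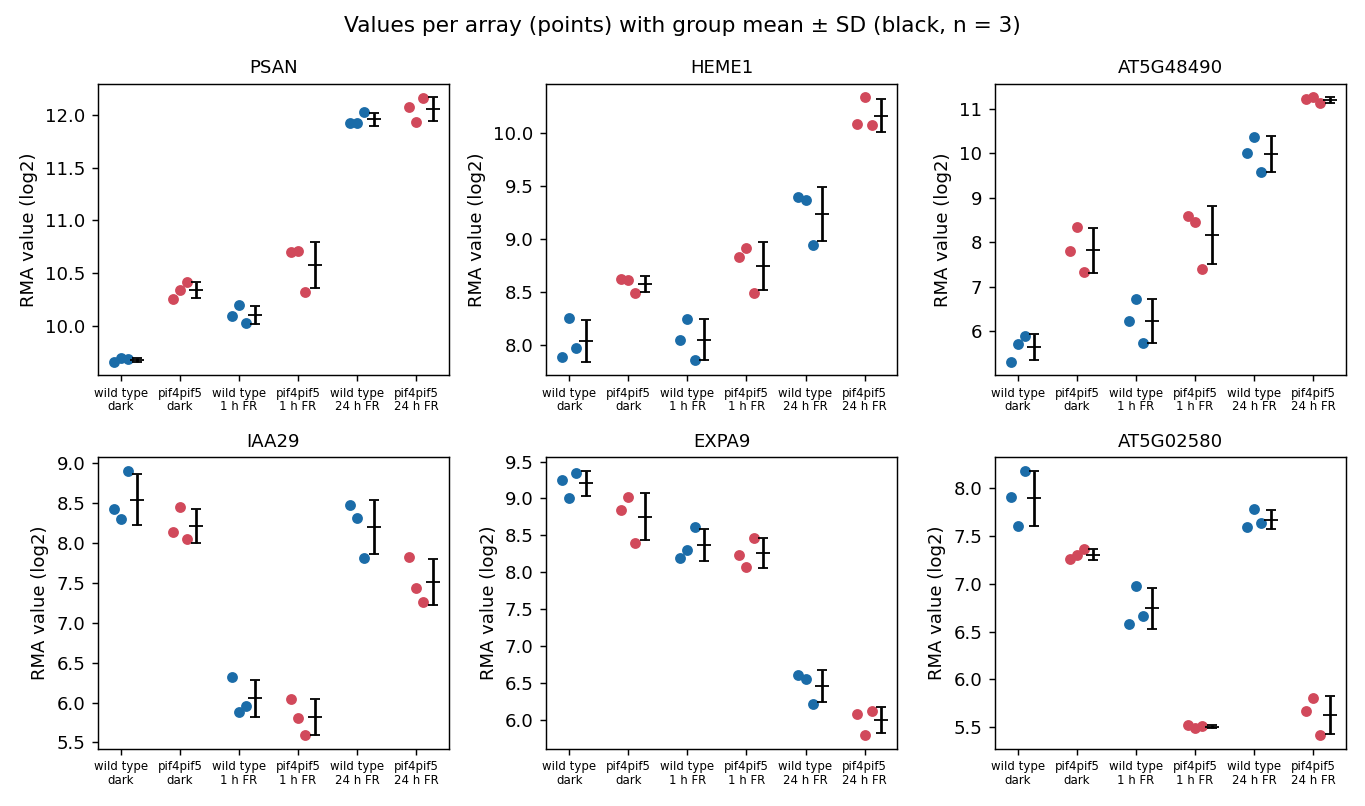
Log2 intensity of PSAN, HEME1, AT5G48490, IAA29, EXPA9 and AT5G02580 by genotype and condition, with 1 point per array and the mean ± SD of 3 arrays (wild type blue, pif4pif5 red). IAA29 falls at 1 h and is near its dark level at 24 h in wild type (8.54, 6.05 and 8.19), and AT5G02580 at 24 h is 7.67 in wild type and 5.63 in the mutant.

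**Figure D5:**
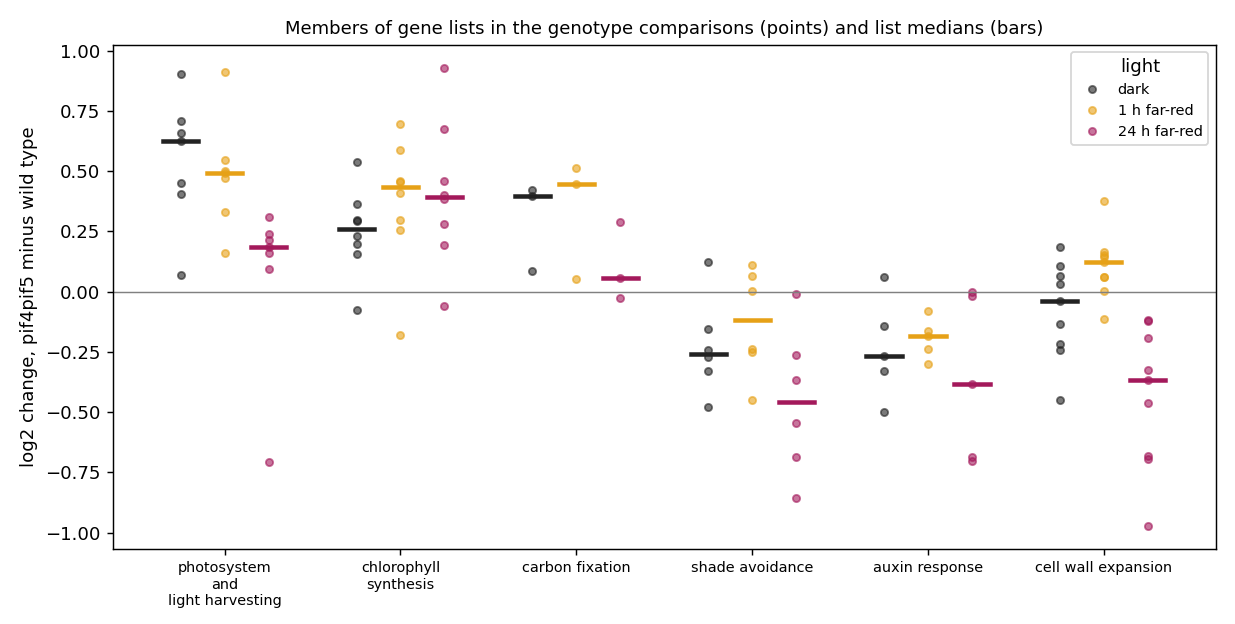
Log2 difference of pif4pif5 from wild type in darkness, at 1 h and at 24 h of far-red light for the measured members of 6 gene lists, with points for genes and lines for medians. The photosystem medians are 0.63, 0.49 and 0.18, and the cell wall expansion medians -0.04, 0.12 and -0.37 (the first is 0.02 with quantile normalization).

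The interaction asks whether the response to far-red light differed between the genotypes. At 24 h AT5G02580 was called: its change from darkness was lower in the mutant by -1.45 on the log2 scale (SE 0.21, adjusted p = 0.0293), a call not kept with the replicate as a block. The other 2 called probe sets have no assigned gene (-2.31, adjusted p = 5.27e-06, and 1.42, adjusted p = 0.0343). The photosystem list rose less in the mutant, with all 7 members negative, 0 called, 2 when adjusted over the list alone and a median of -0.50 (adjusted p = 1.91e-06, but 0.11 with an estimated correlation). PSAN was at -0.56 (SE 0.18, adjusted p = 0.84). All 9 cell wall expansion genes were negative, with 0 called, 0 when adjusted over the list alone and a median of -0.31 (adjusted p = 0.00305, but 0.33 with an estimated correlation). That call was also lost without wild-type dark replicate C (adjusted p = 0.218), wild-type 24 h replicate B (0.0834) or mutant 24 h replicate C (0.131), and the median was -0.50 without wild-type 24 h replicate C. Shade avoidance (median -0.32, adjusted p = 0.125) became called without wild-type 24 h replicate C (0.0397) or mutant 24 h replicate A (0.0472), and carbon fixation (-0.37, adjusted p = 0.228) without wild-type dark replicate B (0.019). Chlorophyll synthesis (0.12, adjusted p = 0.41, and 0.0312 without wild-type dark replicate C), auxin response (-0.06) and flavonoid genes (-0.02, and 0.03 after a shift to one median) were not called. HYH (-0.84), RCA (-0.42), EXPA8 (-0.55) and HEME1 (0.39) were not called.

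Of the 3 calls of the interaction at 24 h 1 was higher and 2 lower (0 and 2 with quantile normalization, 2 and 2 after a shift to one median), with 1338 probe sets at an unadjusted p under 0.05. The count was 118 (112 higher and 6 lower) without wild-type dark replicate A, and 1 without wild-type 24 h replicate B, mutant dark replicate A or B, or mutant 24 h replicate A or C. AT5G02580 lost its call without any 1 of the wild-type 24 h or mutant dark replicates and without mutant 24 h replicate A or C (adjusted p up to 0.142), the probe set at -2.31 kept it, and the one at 1.42 lost it in 8 of 12 fits (up to 0.180). At 1 h limma called 0 probe sets in the interaction, with 440 at an unadjusted p under 0.05, and 1 without wild-type dark replicate A. The photosystem list was then at a median of 0.01, a mean of -0.06 and a downward test direction (adjusted p = 0.479). Without wild-type dark replicate B its median was -0.14 (adjusted p = 0.041). The other lists were not called at 1 h, the largest medians being those of flavonoid (0.37, and called without mutant 1 h replicate C, adjusted p = 7.70e-04) and root marker genes (0.32, adjusted p = 0.0534). The latter became called without wild-type dark replicate B or C, wild-type 1 h replicate B, mutant dark replicate A, or mutant 1 h replicate B or C (adjusted p = 0.041, 0.00357, 0.047, 0.0465, 0.0175 and 0.0181).

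Lists with fewer than 3 measured genes or without any call were as follows. The light signalling list was measured by HYH, the clock list by GI, the phytochrome list by FHL and the seed reserve list by ICL, with the values above. FHL was not called in wild type at 1 h (-0.58, adjusted p = 0.441) or at 24 h (-0.73, adjusted p = 0.1), where the count adjusted over the list alone is 1 for this single gene. In wild type at 24 h EIN3 (0.02) of the ethylene list, LYC (0.40) of the carotenoid list, LIL3:1 (0.55) of the photoprotection list and STZ (-0.75) of the stress and handling list were not called, nor was COR15A of the latter list at 24 h in the mutant (0.74, adjusted p = 0.0593, and 0.00181 without 24 h replicate C). ARR15 was not called at 1 h in wild type (-0.25), and RR16 was not called at 24 h in wild type (0.40). The brassinosteroid, plastid regulator and starvation lists had 0 measured genes. The 3 gibberellin receptor genes gave 0 calls by limma in any comparison. The 3 root markers gave 0 calls too, with a list median of -0.43 at 1 h in wild type and 2 called when adjusted over the list alone (adjusted p = 0.172 for the list, and 0.0088 without wild-type dark replicate C).

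In 2 of 3 tested relations the genotype effect was called by fry as running along the far-red response, and neither of the 2 was called with the replicate as a block. In darkness the mutant's difference from wild type correlated with the wild-type change between 1 h and 24 h over the 1639 probe sets called in the latter (r = 0.520, slope 15.6%; adjusted p = 0.0436 by fry). At 1 h it correlated with the wild-type response at 24 h over 2559 probe sets (r = 0.449, slope 11.8%; adjusted p = 0.0436). At 24 h the relation with the 1 h response over 179 probe sets had r = 0.467 and a slope of 9.92%. It was not called by fry (adjusted p = 0.0679), but it was under both other scalings and without wild-type dark replicate B (r = 0.542, adjusted p = 0.0189). Without dark replicate A r was 0.0260, over the 1685 probe sets called at 1 h in that fit. Fits with an array left out or another scaling took their own called probe sets, so their r are not over the same ones. These 3 relations share no array within a pair, are across probe sets that are not independent replicates, and had r of 0.164, 0.181 and 0.0139 over all probe sets. The first was lost without wild-type dark replicate A (r = 0.333, adjusted p = 0.146), mutant dark replicate A (0.563, 0.0539) or C (0.333, 0.0934), or wild-type 24 h replicate A (0.542, 0.0591) or B (0.516, 0.0974). The relation at 1 h was lost without wild-type dark replicate A (0.480, 0.109) or C (0.233, 0.236), wild-type 1 h replicate A (0.438, 0.0819) or C (0.422, 0.0749), wild-type 24 h replicate A (0.469, 0.0591) or B (0.418, 0.114), or mutant 1 h replicate A (0.458, 0.0899) or B (0.327, 0.118).

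Genotype effects called in darkness or at 1 h had the same direction in the later conditions. The mutant's differences in darkness and at 1 h shared 3 of their 6 calls each, 2 higher and 1 lower, where 6.59e-04 and 1.32e-04 are expected by chance (r = 0.290 over all probe sets). Those at 1 h and 24 h shared 3 lower ones, among them AT5G02580 and AT5G26270, where 0.00857 are expected (r = 0.323), and those in darkness and at 24 h shared 1 lower one, where 0.00286 are expected (r = 0.138). All 6 probe sets called in darkness had the same sign at 1 h and at 24 h (r = 0.990 and 0.990 over the 6), and all 6 called at 1 h had it at 24 h (r = 0.986). Both sets hold the probe set at -3.56, -4.57 and -5.01, which lies far from the others and largely sets these r. It is among the shared lower calls, and PIF4 or PIF5 is not excluded as its target. A shared sign does not mean a kept size. The probe set higher by 1.81 in darkness stood at 12.52 in the mutant and 12.22 in wild type at 24 h. Of the 83 called at 24 h, 73 had the same sign at 1 h and 77 in darkness.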

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

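The tests of the wild-type dark replicates, of the control probe set and, in part, of the photosystem genes were chosen after the results had been seen. Those of other splits of the arrays were fixed before.

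Wild-type dark replicates B and C stood apart from the other 16 arrays, and they belong to the group that serves as the reference for 5 comparisons. A raised background on these arrays is consistent with the unspiked bacterial controls, whose means exceeded the highest of the other 16 arrays by 0.0803 for B and 0.378 for C, and 11 of the 27 controls on B and 22 on C read above all 16. Array scaling alone does not remove the distance between B and C. After quantile normalization it was 0.57, against 0.431 for the largest pair of any other group. For their distances from replicate A scaling stays open. After quantile normalization that of B was 0.0187 and that of C 0.00441 above the same largest pair, with an SD of 0.0659 among such pairs. Light like that of the 1 h treatment is unlikely to account for the distance of these arrays. Their deviations from replicate A followed the mutant's 1 h response with slopes of 0.0477 (SE 0.0203) for B and 0.0687 (SE 0.0249) for C. Both slopes are small but positive, and light of another length or colour was not tested. Hybridizing the same RNA again would separate the array from the seedlings.

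Photosystem and light harvesting genes rose less in the mutant than in wild type at 24 h, by a median of -0.50 over 7 genes, all negative, with 0 called (adjusted p = 1.91e-06 as a list, but 0.11 with an estimated correlation). The dark arrays alone are an unlikely source, because with the 1 h arrays in their place the median was -0.36 (adjusted p = 9.6e-06, but 0.0883 with an estimated correlation). Saturation of bright probe sets stays open. The 326 other probe sets within the range of rise and brightness of the 7 genes had a median of -0.18. That range of brightness, 7.23 to 12.6 in the mutant at 24 h, starts below the upper quartile of those arrays (7.4 to 7.56). Many of the 326 may thus not be bright, so their median cannot show saturation. Their choice by the wild-type rise also biases that value towards a negative one. A head start of the mutant is consistent with its median excess of 0.49 at 1 h, a comparison that uses no dark array. A measurement between 1 h and 24 h would tell whether the mutant reaches the same level earlier.

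The control probe set U12639 read higher on mutant arrays, at 4.81 (SD 0.391) against 3.14 (SD 0.226) for wild type, a difference of 1.67. It was picked because it was the only one of 64 controls called between the genotypes in all 3 conditions. In the mutant it also rose by 0.735 (SE 0.153) from darkness to 24 h of far-red light. Array background is unlikely to be the reason, as the unspiked bacterial controls differed by -0.0644. For mislabelled arrays, the 0 arrays inside the range of the other genotype only restate the pattern. A probe set without an assigned gene (-3.56 in darkness) split the arrays alike, at 6.41 to 8.84 in wild type and 3.21 to 3.79 in the mutant. Single arrays exchanged between the genotypes would break such a split, so these values argue against that. This probe set was itself picked for its genotype difference. Labels exchanged for whole genotypes or between conditions stay open. RNA made from inserted DNA in the mutant lines was not tested: the 9 mutant arrays above the highest wild-type array are the pattern itself, and the tables used do not name the target of the probe set. Its sequence, compared with that of any DNA inserted in the mutant lines, would settle this.

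Between the genotypes the response to 24 h of far-red light differed by -1.45 for AT5G02580, and by -2.31 and 1.42 for 2 probe sets without an assigned gene. For the cell wall expansion list it differed by a median of -0.31, not called with an estimated correlation (adjusted p = 0.33).

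Splits of 6 arrays into 3 against 3 number 10, too few for a share under 0.05. The real count and the highest of the other splits were 179 and 0 for 1 h in wild type, 2559 and 52 for 24 h in wild type, 159 and 0 for 1 h in the mutant, 2605 and 0 for 24 h in the mutant, and 1639 and 0 for 24 h against 1 h. They were 6 and 7 for the genotypes in darkness, where 2 of the 10 splits gave as many, 6 and 0 at 1 h and 83 and 1 at 24 h, where 1 of the 10 did. For the relation of the genotype effect to the light response the real r and the highest other were 0.520 and 0.598 in darkness (2 of 10 splits as large), 0.449 and 0.536 at 1 h (4 of 10) and 0.467 and 0.413 at 24 h (1 of 10).

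For the interactions 100 splits of the genotypes, the real one included, were taken within the dark and the far-red arrays. At 24 h 15 of them gave 3 calls or more, so chance is not excluded. The highest other counts were 177, 119 and 31, which point to a structure of the samples that was not tested further. At 1 h all 100 gave as many as the real 0, with a highest other of 9. Of 100 groupings of the 18 arrays, 2 gave at least 38 called lists, the real one with 38 included. The other 99 gave between 4 and 41 with a median of 20, so a number as high as the real one was rare. These groupings break light and genotype together, so they do not bear on the list calls between the genotypes or in the interactions. Many calls arise without the groups, so a list called only with the preset correlation is weak evidence.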

How the results depend on the processing

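Array weights, the removal of the 3 arrays of lowest weight (wild-type dark replicates B and C and mutant 24 h replicate B) and the tests of families were chosen after the data had been seen. The causes of the changes given here were not tested.

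Among 10 comparisons the number of called probe sets moved with several settings. Without the 40% dimmest probe sets the genotypes at 1 h gave 12 calls. A trended and robust prior gave 17 for the genotypes in darkness and 16 at 1 h, and quantile normalization 11 in darkness. Fits on the compared groups only gave 59 for 1 h and 756 for 24 h in wild type, 0 for the genotypes in darkness (1654 at an unadjusted p under 0.05 in the fit to all arrays), 13 at 24 h and 1 for the interaction at 24 h. A 2-fold minimum left 116 at 1 h and 787 at 24 h in wild type, 869 at 24 h in the mutant, 47 for the genotypes at 24 h and 609 for 24 h against 1 h.

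Without probe sets of several genes or none the counts were 39 (wild type, 1 h far-red against dark), 1220 (wild type, 24 h far-red against dark), 30 (pif4pif5, 1 h far-red against dark), 1181 (pif4pif5, 24 h far-red against dark) and 743 (wild type, 24 h against 1 h far-red), with 1, 3 and 40 for the genotypes in darkness, at 1 h and at 24 h, and 1 for the interaction at 24 h. In the same order from the second on, array weights gave 1531, 474, 4607 and 3551, and 3, 425 and 225 for the genotypes. Without the 3 arrays of lowest weight there were 278 calls at 1 h in the mutant, 2864 for 24 h against 1 h, 16 for the genotypes at 1 h, and 3 and 5 for the interactions. The genotype count at 1 h lay between 2 and 425 over all alternatives.

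With the replicate as a block the counts were 208 (wild type, 1 h far-red against dark), 3051 (wild type, 24 h far-red against dark), 200 (pif4pif5, 1 h far-red against dark), 2961 (pif4pif5, 24 h far-red against dark) and 1976 (wild type, 24 h against 1 h far-red), and 23, 39 and 118 for the genotypes, with 0 and 1 for the interactions. Mean correlations of the deviations of same-letter arrays ranged from -0.0105 to 0.282 over the pairs of groups, the lowest being the only negative one. A shared effect of the letters is therefore not excluded. All 3 letters passed 0.1 for wild type at 1 h and 24 h (mean 0.186), where the counts are 1976 with the block and 1639 without, and for wild type in darkness and the mutant at 24 h (0.282). Means were as high in other pairs, such as the genotypes in darkness (0.249), without every letter passing. In the interaction at 24 h the call of AT5G02580 was not kept with the block.

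Leaving out 1 array at a time gave 98 to 1685 calls at 1 h and 1676 to 3814 at 24 h in wild type, 84 to 177 and 1543 to 2284 in the mutant, 1077 to 1404 for 24 h against 1 h, 2 to 702, 2 to 52 and 21 to 178 for the genotypes in darkness, at 1 h and at 24 h, 0 to 1 for the interaction at 1 h and 1 to 118 for that at 24 h. Of 90 list tests 38 were called, 34 to 45 with 1 array left out, 39 with the replicate block and 14 with an estimated correlation.

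The genotype effect along the light response: pif4pif5 against wild type, 24 h far-red with wild type, 1 h far-red against dark (r = 0.467) became called with quantile normalization (r = 0.451, adjusted p = 0.0454), after a shift to one median (r = 0.451, 0.0272) and without probe sets of several genes or none (r = 0.594, 0.0225). With the replicate as a block it was not called in darkness (r = 0.504, adjusted p = 0.0729) or at 1 h (r = 0.399, 0.0819), nor was it over all genes (r = 0.164, 0.167 in darkness and r = 0.181, 0.122 at 1 h). Without the 3 arrays of lowest weight the genotype effect along the light response: pif4pif5 against wild type, 1 h far-red with wild type, 24 h far-red against dark was 0.360 (adjusted p = 0.0997). With 1 array left out r ranged from 0.333 to 0.596 in darkness, from 0.233 to 0.544 at 1 h and from 0.0260 to 0.580 at 24 h. Each of these r is over the probe sets called in its own fit.

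The list medians that changed sign with a call were those of chlorophyll synthesis at 1 h in wild type, 0.11 without dark replicate B and 0.06 without 1 h replicate C (-0.0888 to 0.11 with 1 array left out), and of photosystem genes in the interaction at 1 h, -0.14 without wild-type dark replicate B (-0.16 to 0.18). Single-probe-set results were counted for the named genes, list members of low p and the probe sets of largest change without an assigned gene. Of their other alternatives 3059 left the call as reported, 212 ended one and 56 made one, with 0 reversed. For lists the counts were 1440, 53 and 42.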

Other observations

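Families of related genes and most tests in this part were chosen after the data had been seen. The exceptions were the count of calls in the direct contrast of 24 h with 1 h and the flanks of the mutated genes.

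Among families that the fixed lists do not hold, the beta-tubulin genes TUB1 and TUB6 fell after 24 h of far-red light in both genotypes. In the mutant 4 of 5 measured TUB genes fell, TUB1 by 3.32 (SE 0.27), TUB6 by 0.99, TUB5 by 0.60 and TUB7 by 0.49, with a median of -0.60 (adjusted p = 1.54e-04, but 0.859 with an estimated correlation). In wild type TUB1 (-2.76) and TUB6 (-0.45) fell, with the family not called (median -0.35, adjusted p = 0.131), and between the genotypes at 24 h TUB6 was lower in the mutant by -0.68 (SE 0.13, adjusted p = 0.0192). The TUB medians were negative in these 3 comparisons under both other scalings too. Of 15 IQD genes, which encode calmodulin-binding proteins, 7 fell and 2 rose at 24 h in the mutant, and 5 fell and 2 rose in wild type, with neither family test called (adjusted p = 0.0815 and 0.445). IQD26 fell by 1.86 and 1.44, and IQD24 rose by 1.91 and 1.27, in the mutant and in wild type. Of 14 genes for SWEET sugar transporters, SWEET1, SWEET2 and SWEET17 rose at 24 h in both genotypes, by 1.09, 0.72 and 1.03 in the mutant and by 0.97, 0.95 and 1.07 in wild type, while SWEET3 fell by 0.81 in the mutant.

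Genes of the plastid genome, measured by 69 probe sets, stood lower in the mutant at 1 h by a median of -0.39 with 0 called by limma (adjusted p = 1.6e-08 as a set, but 0.991 with an estimated correlation). The median was -0.37 with quantile normalization and -0.38 after a shift to one median. Their change from darkness at 1 h was -0.64 in the mutant (adjusted p = 5.89e-10, but 0.96 with an estimated correlation), and the difference between the genotypes in that change was -0.43 (adjusted p = 1.47e-10, but 0.906 with an estimated correlation). The members move together between arrays, so these shifts are not established.

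The genotype effect may grow between 1 h and 24 h of far-red light, which would give the larger number of calls at 24 h. That order of the counts, 6 and 83, is not firm, since array weights turn it to 425 at 1 h and 225 at 24 h. In the direct contrast of the genotype effect at 24 h with that at 1 h, 1 probe set was called, one without an assigned gene, at -1.90 (SE 0.18, adjusted p = 1.2e-04), and 683 had an unadjusted p under 0.05. Of the 83 probe sets called at 24 h, 73 had the same sign at 1 h, and 26 of these had an unadjusted p under 0.05 there. Over all 83 the median change in the 24 h direction was 0.24 at 1 h, against a median size of 1.04 at 24 h. The sizes at 24 h are those of selected probe sets and so run high. The 1 h arrays did not have the wider spread, since their median residual SD differed from that of the 24 h arrays by -0.0622. All groups share one spread in the model, so this comparison cannot show whether spread affects the counts of 6 and 83. Among lists, cell wall expansion genes had a median of -0.39 in the direct contrast, with 9 of 9 negative (adjusted p = 7.5e-06, but 0.0883 with an estimated correlation), and shade avoidance genes one of -0.37, with 6 of 6 negative (adjusted p = 0.0174, but 0.113 with an estimated correlation). Photosystem genes had one of -0.36, with 7 of 7 negative (adjusted p = 9.6e-06, but 0.0883 with an estimated correlation). For these the mutant's excess at 1 h (median 0.49) shrank, which is not growth of the genotype effect.

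Changes on the flanks of the mutated genes were looked for among the 20 measured neighbours of PIF4 and the 20 of PIL6, in the gene order of assembly TAIR10.1. Called genes among them numbered 0 by limma, so changes on the flanks of the mutated genes do not account for the genotype calls of single-gene probe sets. Genes called between the genotypes at 24 h did not lie next to each other more often than random draws did: 1 pair was found within 3 measured genes of each other, against a mean of 0.390 in 10000 draws (permutation p = 0.327). The pair was GH3.9 (1.04) and AT2G47780 (-1.04), which changed in opposite directions.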
